A study of Homo sapiens with 4 samples.

How the data were processed

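RNA from RWP-1 cells, a human pancreatic cancer cell line, was profiled on 4 single-channel oligonucleotide arrays. Per the labels' protocols, 100 ng of total RNA per sample was labelled with biotin using a whole-transcript kit. The 2 groups were control cells, labelled Ctrl, and cells treated with rGAL1, with 2 arrays in each. rGAL1 is taken here to be recombinant galectin-1, a secreted lectin that binds galactose-containing sugars; the labels give only the short form, with no dose, time or vehicle. Groups and replicate numbers came from the sample titles. The labels of the array called rGAL1 2 disagree with each other: its title, its source name and the series' count of 2 and 2 place it in the rGAL1 group, and its treatment field reads as control. It was kept in the rGAL1 group, and counting it as a control was one of the alternatives. The labels do not say whether the arrays of a group came from separate cultures. The p-values of single probe sets thus measure only the spread between these arrays, which may be technical.

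The deposited values are log2 expression values per probe set. RMA and limma are named in the submitters' processing notes, and the versions and settings are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a set, and it compresses differences of dim probe sets. The median deposited log2 value lay between 4.69 and 4.72 on the 4 arrays, so the arrays were on a common scale. No sample column of the table was left unused. The table held 53617 probe sets, of which 16098 had exactly 1 gene symbol in the platform annotation, none had several, and 37519 had none and stay unnamed here. All 16098 were matched to a current gene record by Entrez ID, and no symbol changed. They covered 14884 genes, 779 of them with more than 1 probe set; the brightest probe set over the 4 arrays represented such a gene. No named probe set belonged to LGALS1, PLAT or CDH1, so these genes are not analysed here. The table gives no detection call. The dim level was the median of the probe sets' means, 4.70 on the log2 scale, because only 1 olfactory receptor probe set was named and the preferred reference needed at least 50. In all, 2113 probe sets carried the same 4 values as another probe set.

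All probe sets were compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, no block), with two-sided p-values and Benjamini-Hochberg adjustment over the 53617 probe sets, at an adjusted p under 0.05. The fit left 2 residual degrees of freedom and drew 2.75 prior degrees of freedom from all probe sets. Differences are rGAL1 minus Ctrl on the log2 scale, with a standard error (SE) and a 95% interval from the moderated fit. On data simulated for this comparison over 53617 probe sets, the test called 0 of 66 probe sets changed by 0.5 log2 units, 0 of 67 changed by 1 unit and 42 of 67 changed by 2 units, with 2 false calls.

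Before the data were examined, 36 gene lists were fixed from general knowledge. The lists covered pathways linked to galectin-1 and pancreatic cancer, stress and metabolic programmes, and markers of pancreatic and other cell types. Of these, 34 had at least 5 named genes and were tested with camera, which compares a list with all other genes, using the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The galectin list and the list of replication-dependent histones had 0 named members and were not tested. Camera with an estimated correlation and fry, a rotation test of the list on its own, were run beside it. At the preset correlation, camera p-values weigh a list against the spread across genes. They take its members as nearly independent and do not measure how far a list varies between arrays. In simulations of the sterol list in 14884 genes with a shift of -0.275 log2 units, camera with the preset correlation called it in 100 of 100 runs and with an estimated correlation in 0 of 100. With no shift, the preset setting called it in 0 of 100 runs with independent members. With a correlation of 0.14 among its members and no shift, it called the list in 2 of 100 runs. The correlation estimated for the sterol list was 0.137, on 2 residual degrees of freedom. Estimates were higher for the fatty acid list (0.20) and the G2/M list (0.43), which were not simulated. The 2 of 100 therefore does not give the rate of false calls for those lists. Each list's median was also placed among 10000 random lists of the same size matched on mean expression.

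The rule for named genes, fixed beforehand, took up to 12 genes per direction with the largest differences among those past the threshold, with both rGAL1 arrays on one side of both Ctrl arrays and a mean above the dim level. As no probe set passed, the places were filled in the same way with genes at an unadjusted p under 0.05, leaving out small RNAs, uncharacterised loci and receptor segments. Up to 3 members per list at an unadjusted p under 0.05 and 5 fixed genes (EGFR, GLI1, VIM, MKI67 and VEGFA) were added. In the report, further members of the lists are named as examples, chosen after their values were seen.

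Alternatives covered the replicate number as a block, the variance prior, a filter on dim probe sets, the normalization, the annotation, the label of rGAL1 2, the threshold, the list test and leaving out each array. No genome build is given in the sources used here, and no coordinates are printed.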

Results

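Transcript levels were measured in RWP-1 cells, an established line of pancreatic cancer cells, without treatment (Ctrl, n = 2 arrays) and after rGAL1, taken to be recombinant galectin-1 (n = 2 arrays). The design asks which transcripts the added lectin changes. The values are log2 RMA expression per probe set, and the number of arrays limits the precision: the median SE of a difference was 0.13 log2 units over all 53617 probe sets and 0.11 over named genes above the dim level. Arrays of the same group were no closer to each other than arrays of different groups. The SD of the difference between 2 arrays over all probe sets was 0.30 for the Ctrl pair, 0.29 for the rGAL1 pair and 0.27 to 0.30 for the 4 pairs across groups. The array rGAL1 2 carries conflicting labels, as described for the processing, and was analysed as rGAL1.

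Genes of cholesterol synthesis were lower, as a group, in rGAL1-treated cells. Of 18 measured members of the sterol synthesis and SREBP2 target list, 17 had lower means in rGAL1, and in all of these 17 both rGAL1 arrays lay below both Ctrl arrays; this separation was found in 17% of all named genes, and chance gives 16.7%. The list's median difference was -0.27 log2 units, a 1.21-fold lower level, and the list was called by camera (limma, adjusted p = 4.1e-14, preset correlation). The call was lost with an estimated correlation (camera adjusted p = 0.787) and with fry (adjusted p = 0.252). Camera with an estimated correlation also called a simulated shift of this size in 0 of 100 runs. It called 0 lists here, so not passing under it does not tell the lists apart. Fry also called 0 lists, and 0.252 was its smallest adjusted p for any list. The sterol list's unadjusted fry p was 0.00765. Fry was not run on the simulated shift, so how often it would call one is not known. At the preset correlation, the camera p-value takes genes as nearly independent and does not measure how far the list varies between arrays. The median difference was -0.24 between the arrays numbered 1 and -0.32 between those numbered 2. Leaving out rGAL1 2, whose labels conflict, left a median of -0.25, and counting it as a control gave -0.16. Both fits leave rGAL1 1 as the only array of its group, with no spread of its own.

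The largest differences in this list were those of ACAT2, an acetyl-CoA acetyltransferase at the entry to the pathway, and INSIG1, which retains the SREBP complex in the endoplasmic reticulum and is itself an SREBP target. ACAT2 measured 8.88 ± 0.11 in Ctrl and 8.40 ± 0.040 in rGAL1 (log2, SD, n = 2), a difference of -0.48 (SE 0.11). INSIG1 measured 9.22 ± 0.13 and 8.75 ± 0.0039 (log2, SD, n = 2), a difference of -0.47 (SE 0.11). IDI1, an isomerase of the isoprenoid units, differed by -0.38 (SE 0.10). Among other enzymes of the route, HMGCS1, which makes the substrate of the rate-limiting reductase, differed by -0.28, MVK by -0.30, MVD by -0.36, FDPS by -0.21, SQLE by -0.33 and DHCR7, which catalyses a final step, by -0.37. STARD4, a sterol carrier, differed by -0.27 and the transcription factor gene SREBF2 by -0.13. PMVK was the 1 member with a higher mean, by 0.028. In the list, 9 members had an unadjusted p under 0.05; 0 passed when adjusted over all probe sets (limma) and 0 when adjusted over the list alone, where the smallest value was 0.0573.

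**Figure D1:**
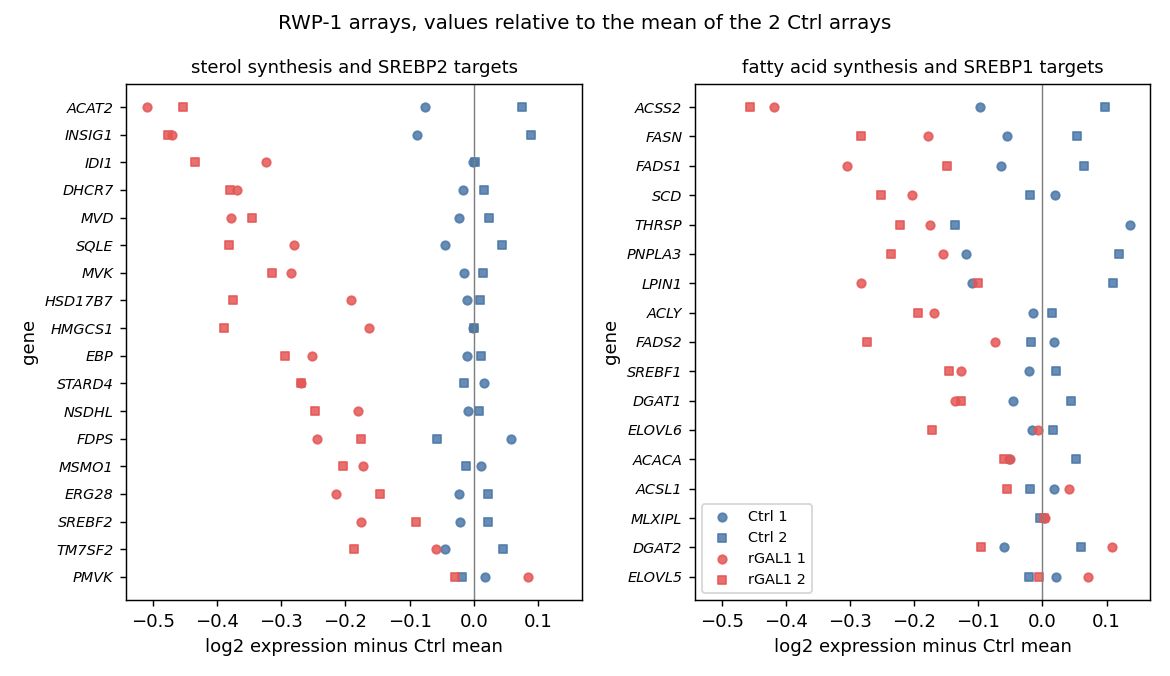
Log2 expression of each array minus the mean of the 2 Ctrl arrays (horizontal axis, log2 units) for the measured genes of the sterol list (left, 18 genes) and of the fatty acid list (right, 17 genes); each symbol is 1 array. For 17 of the 18 sterol genes and 10 of the 17 fatty acid genes both rGAL1 arrays lie below both Ctrl arrays.

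Fatty acid synthesis genes and SREBP1 targets were also lower as a group. Of 17 measured members, 14 had lower means in rGAL1, and in 10 both rGAL1 arrays lay below both Ctrl arrays, with 0 separated the other way. The median difference was -0.17 log2 units, a 1.13-fold lower level (camera, limma, adjusted p = 0.000137 with the preset correlation, adjusted p = 0.787 with an estimated correlation, and adjusted p = 0.252 with fry). ACSS2, which activates acetate to acetyl-CoA, measured 7.80 ± 0.14 in Ctrl and 7.36 ± 0.027 in rGAL1 (log2, SD, n = 2), a difference of -0.44 (SE 0.12). Fatty acid synthase, FASN, differed by -0.23, the desaturases SCD and FADS1 by -0.23 each, and ATP citrate lyase, ACLY, by -0.18, while ACACA (-0.055), ELOVL5 (0.033) and DGAT2 (0.0063) lay near 0. No gene is in both lists. In the fatty acid list, 1 member, ACSS2, had an unadjusted p under 0.05 (limma). None passed over all probe sets or adjusted over the list alone. The median difference was -0.091 between the arrays numbered 1 and -0.19 between those numbered 2. Without Ctrl 2 the median was -0.086. With rGAL1 2 counted as a control the median was -0.079 and the call was lost. Each of these 2 fits leaves 1 array in a group, with no spread of its own.

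The remaining 32 lists did not pass, with medians between -0.069 and 0.090 log2 units and a smallest camera adjusted p of 0.0895. Against random lists matched on expression, the medians of 4 of the 32 lay outside the middle 95%: G2/M above it, and Wnt targets, ribosomal proteins and oxidative phosphorylation below it. The medians of the YAP and SRF, TGF-beta and ATF4 lists differed in sign between normalizations, and those of the Notch, hypoxia and angiogenesis lists turned only on centring the arrays on their medians, which moves all genes alike. Leaving out 1 array changed the sign of the median in 17 of the 32 lists, and changed the sign or moved the median by over 1.5 times in 29. The exceptions were the ERK, Wnt and unfolded protein response lists. By the same measure the called fatty acid list also moved, from -0.17 to -0.086 without Ctrl 2. The sterol list did not, with medians from -0.30 to -0.25. With an intensity trend in the variance prior, 7 lists passed: beside the sterol and fatty acid lists these were G2/M and mitosis, unfolded protein response, Wnt targets, ribosomal proteins and oxidative phosphorylation, with adjusted p between 0.000783 and 0.0371 for these 5. None of the 5 passed with an estimated correlation in the fit without the trend (camera adjusted p = 0.787 for each). That setting also missed the simulated sterol shift, so it cannot decide on these lists.

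**Figure D2:**
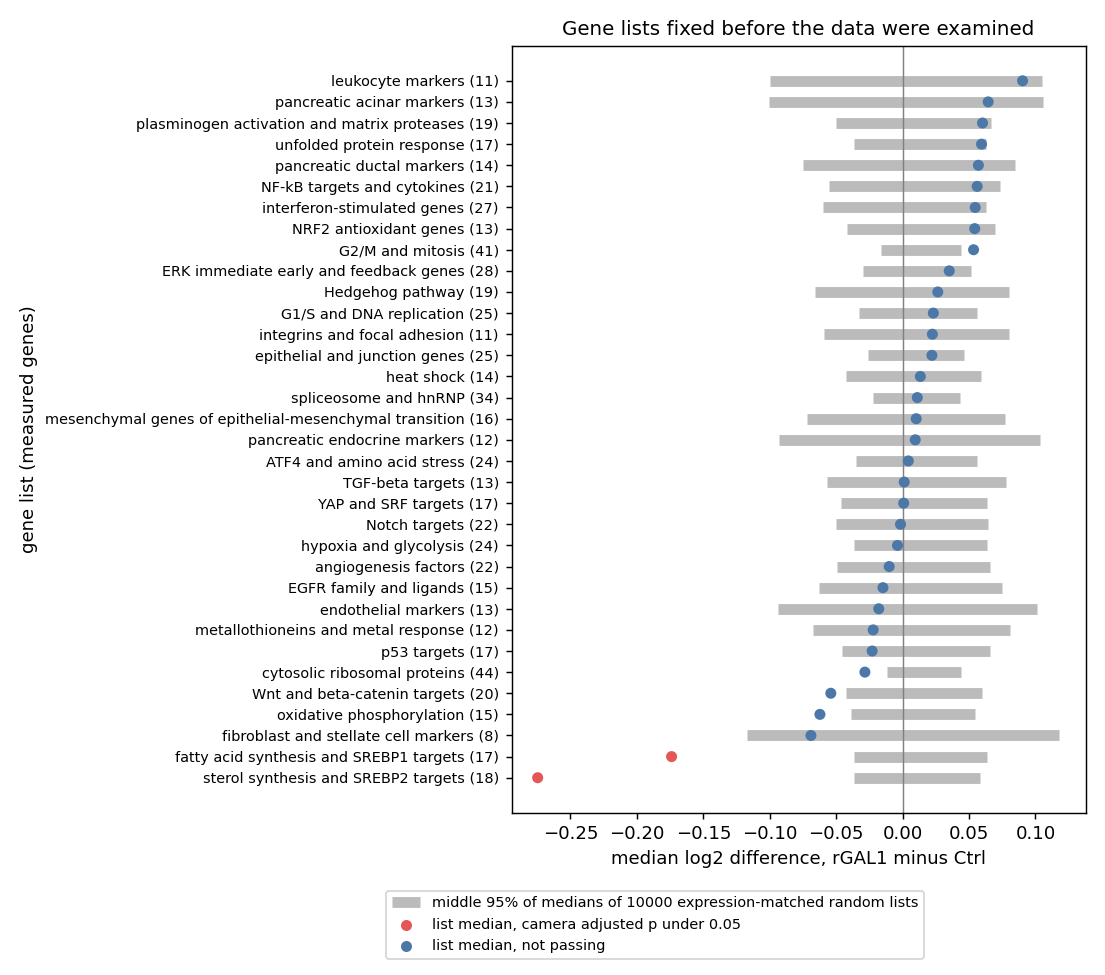
Median log2 difference, rGAL1 minus Ctrl, of each of the 34 tested gene lists (points, with the number of measured genes in parentheses) beside the middle 95% of the medians of 10000 expression-matched random lists (grey bars). The sterol list, at -0.27, and the fatty acid list, at -0.17, have the lowest medians; the other 32 lie between -0.069 and 0.090, 4 of them outside their grey bar.

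Among growth-related lists, 31 of 41 mitotic genes had higher means in rGAL1, with a median of 0.053 (camera adjusted p = 0.0895; adjusted p = 0.787 with an estimated correlation). KIF11, a spindle motor, differed by 0.22 (SE 0.10) and NDC80, a kinetochore component, by 0.21 (SE 0.11). The list's value depended on single arrays: it passed without Ctrl 1 (median 0.092, camera adjusted p = 0.00292) and without rGAL1 2 (median 0.11, adjusted p = 0.0323), and did not without Ctrl 2 (median 0.025, adjusted p = 0.875) or without rGAL1 1 (median 0.020, adjusted p = 0.522). MKI67, a proliferation marker, differed by 0.095 (95% interval -0.16 to 0.35), and the 25 genes of the G1/S list had a median of 0.023. Immediate early and feedback genes of ERK signalling had a median of 0.035 over 28 genes. EREG, an EGFR ligand, was 1 of these and measured 5.26 ± 0.087 in Ctrl and 5.67 ± 0.23 in rGAL1 (log2, SD, n = 2), a difference of 0.41 that was 0.25 without rGAL1 1. EGFR differed by 0.045 (95% interval -0.24 to 0.33), and by -0.023 without Ctrl 1. The EGFR family list had a median of -0.015 over 15 genes, and EGF in it, dim at 4.50 in Ctrl, differed by -0.29 (SE 0.11).

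Hedgehog pathway genes, of interest because galectin-1 has been linked to this pathway in the pancreas, had a median of 0.026 over 19 genes (camera adjusted p = 0.614). GLI1, a pathway target with a mean below the dim level, differed by 0.12 (95% interval -0.26 to 0.49), and by -0.044 without Ctrl 1. PTCH1 differed by -0.0056. Wnt target genes were split, with 11 of 20 lower and a median of -0.054 (camera adjusted p = 0.184). The feedback genes AXIN2 and NKD1 each differed by -0.31, with SEs of 0.098 and 0.11, and the secreted inhibitor WIF1, dim at 4.00 in Ctrl, by -0.38 (SE 0.12), while MYC (0.049) and CCND1 (-0.055), which many pathways control, lay near 0. Notch targets had a median of -0.0016 over 22 genes, with HEY1 (dim, -0.39), HES2 (-0.34, and -0.22 without rGAL1 2) and HES6 (-0.30) as the members at an unadjusted p under 0.05. The YAP and SRF list had a median of 0.00081 and the TGF-beta list 0.0012. In them ANKRD1, a YAP target, differed by -0.37 (SE 0.10) and BAMBI, a decoy receptor of the TGF-beta family, by -0.36 (SE 0.12).

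Among the genes named by the fixed rule, the largest difference was in a matrix protease. MMP1, interstitial collagenase, measured 5.68 ± 0.26 in Ctrl and 6.44 ± 0.23 in rGAL1 (log2, SD, n = 2), a difference of 0.76 (SE 0.19), or 1.69-fold, that did not pass (limma, adjusted p = 0.919). MMP10 differed by 0.29 (SE 0.11). The list of plasminogen activation and matrix proteases as a whole had a median of 0.060 over 19 genes (camera adjusted p = 0.380), and of 0.019 without Ctrl 2. Mesenchymal genes had a median of 0.010 over 16 genes, and the epithelial and junction list 0.022 over 25 (0.0045 without Ctrl 2). VIM, an intermediate filament of mesenchymal cells, differed by 0.11 (95% interval -0.15 to 0.37), and by 0.069 without rGAL1 1; its dimmer probe sets gave -0.13 and 0.12. Integrin and focal adhesion genes had a median of 0.022 over 11 genes.

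Interferon-stimulated genes had higher means in 19 of 27, with a median of 0.055 (camera adjusted p = 0.0989; adjusted p = 0.787 with an estimated correlation). That median was 0.012 without rGAL1 1 (16 of 27 higher) and 0.099 without Ctrl 1. IFIH1, a sensor of double-stranded RNA, differed by 0.32 (SE 0.11), whereas IFIT2 (0.38, and 0.23 without Ctrl 2) and the chemokine gene CXCL10 (0.35) were below the dim level of 4.70 in both groups. NF-kB targets and cytokines had a median of 0.056 over 21 genes, and of 0.0022 without Ctrl 1. In this list CCL2, also dim, differed by 0.45 (SE 0.15). The unfolded protein response list had a median of 0.059 over 17 genes, with OSTC, a subunit of the oligosaccharyltransferase complex, at 0.34 (SE 0.11). The ATF4 list had a median of 0.0043, with TRIB3 at -0.32 (SE 0.10). NRF2 antioxidant genes (median 0.054), heat shock genes (0.013), metallothioneins (-0.022) and p53 targets (-0.023) did not pass. In the hypoxia and glycolysis list, with a median of -0.0039 over 24 genes, VEGFA differed by -0.29 (SE 0.10) and BNIP3L by -0.32 (SE 0.10). Among angiogenesis factors, with a median of -0.010 over 22 genes, THBS1 differed by -0.33 (SE 0.10). Oxidative phosphorylation (median -0.062), ribosomal proteins (-0.028) and spliceosome genes (0.011) did not pass.

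Markers of pancreatic and other cell types gave no list past the threshold. The medians were 0.057 for pancreatic ductal markers, 0.064 for acinar, 0.0095 for endocrine, -0.069 for fibroblast and stellate cell, -0.018 for endothelial and 0.090 for leukocyte markers. Leaving out 1 array changed the sign for the acinar list (-0.015 without rGAL1 2), the endocrine list (-0.0047 without Ctrl 1), the fibroblast list (0.026 without Ctrl 2) and the endothelial list (0.045 without Ctrl 1, 0.021 without Ctrl 2 and 0.050 without rGAL1 1). The leukocyte median was 0.049 without Ctrl 2, and the ductal median 0.023 without rGAL1 1. Single members at an unadjusted p under 0.05 were CTRB1, a chymotrypsinogen of acinar cells, at 0.61 (SE 0.18), CEACAM6, dim in both groups, at 0.29 (SE 0.11) and CD68, a lysosomal protein used as a macrophage marker, at 0.39 (SE 0.12). Median, mean and camera direction differed in sign for 8 lists, all with a camera adjusted p of at least 0.510: mesenchymal, epithelial, YAP and SRF, TGF-beta, ATF4, metallothionein, endothelial and spliceosome.

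Gene by gene, no probe set passed at an adjusted p under 0.05 in limma, where the smallest adjusted p was 0.919. At an unadjusted p under 0.05 there were 2807 probe sets, 1275 higher and 1532 lower in rGAL1, which is 5.24% of those tested where chance gives 5%. Among the 14884 named genes these were 444, with 211 higher and 233 lower, a share below 5%. With the variance prior drawn from the probe sets with 1 symbol alone, 1006 of 16098 were under 0.05. The share of named genes thus depends on the prior. By the fixed rule, the 24 genes with the largest differences ranged from 1.36-fold to 1.69-fold. On the higher side, MMP1 and CTRB1 were followed by GPCPD1, which cleaves glycerophosphocholine, at 0.57 (SE 0.11), then ODAD4 at 0.53, the pseudogene HNRNPA1P33 at 0.50, KRABD5 at 0.49, TLR3, an endosomal receptor for double-stranded RNA, at 0.49 (SE 0.15), the zinc finger gene ZNF350 at 0.49, WAKMAR2 at 0.49, EXTL2 at 0.48, YY1AP1 at 0.47 and TRIM16 at 0.47. On the lower side, IL32, a proinflammatory cytokine, measured 7.31 ± 0.12 in Ctrl and 6.71 ± 0.16 in rGAL1 (log2, SD, n = 2), a difference of -0.61 (SE 0.13). FGF22 differed by -0.55 (SE 0.20), ERLN by -0.52, TAL2 by -0.50, the long noncoding RNA MIAT by -0.48, SPRR1A, a protein of the cornified envelope, by -0.48, and ACAT2 and INSIG1 by the values given above. RRP7BP differed by -0.46, NPAP1P9 by -0.44, NHLRC1 by -0.44 and ACOT1 by -0.44. Some of these genes were dim in 1 group. ODAD4, KRABD5, TLR3, ZNF350 and YY1AP1 had Ctrl means below the dim level, and ERLN, NHLRC1 and ACOT1 had rGAL1 means below it. MIAT had another, dimmer probe set at -0.068 and WAKMAR2 another at 0.15, and the further probe sets of NPAP1P9 gave -0.36, 0.071 and -0.32. Leaving out 1 array moved 6 of these 24 differences by over 1.5 times. Without Ctrl 2 the difference was -0.28 for FGF22, -0.31 for MIAT, 0.27 for ZNF350, 0.27 for TRIM16 and 0.33 for TLR3, and without rGAL1 1 it was 0.30 for YY1AP1. RRP7BP, NPAP1P9 and HNRNPA1P33 are pseudogenes whose probes can also bind transcripts of related genes.

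**Figure D3:**
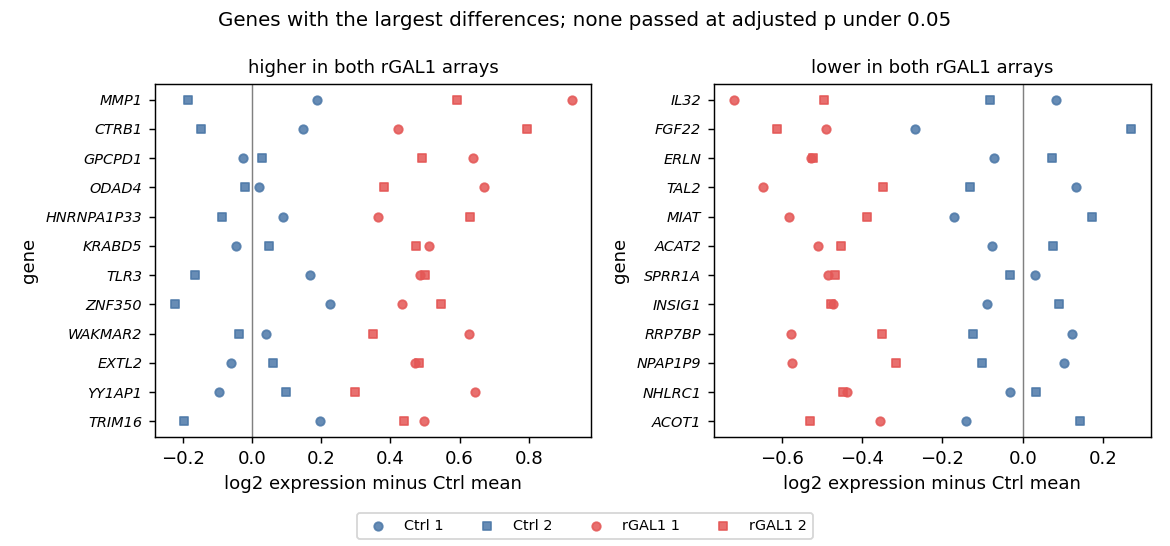
Log2 expression of each array minus the mean of the 2 Ctrl arrays (horizontal axis, log2 units). Shown are the 12 genes with the largest differences under the fixed rule in each direction, higher (left) and lower (right). The rule required separated arrays, a mean above the dim level and an unadjusted p under 0.05 (limma). It left out small RNAs, uncharacterised loci and receptor segments. Each symbol is 1 array. MMP1, at 0.76, has the largest difference on the higher side and IL32, at -0.61, on the lower side, and none passed the test.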

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

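Leaving out the probe sets numbered below the first named one was chosen after seeing the data; the other settings were planned. With limma, 0 probe sets passed an adjusted p under 0.05 in each fit, the fits without 1 array (0 to 0) and the replicate block included, and 0 passed an adjusted p under 0.1. The replicate block left 0 probe sets and 2 lists called. The deviations of same-numbered arrays from their group means did not correlate across probe sets (r = -0.048). The numbers were therefore not taken to pair the arrays. This r does not exclude an effect shared by same-numbered arrays in some genes. Comparing the arrays numbered 2 with those numbered 1 gave a smallest adjusted p of 0.0873 (limma), against 0.919 for rGAL1 against Ctrl. That comparison also called the G2/M list (camera). Counting at an unadjusted p under 0.05 gives 2807 probe sets, by construction more than an adjusted threshold. It gives 1641 above the dim level and 1006 with 1 symbol, where fewer were tested and the prior was drawn anew. In the fit to all probe sets, 444 of 14884 named genes were under 0.05, so the count of 1006 also depends on the prior. The count of called lists, 2, was 7 with an intensity trend in the prior, where the cause was not tested, and 2 to 3 without 1 array. It was 0 with an estimated correlation and 0 with fry, where the medians stay at -0.27 (sterol) and -0.17 (fatty acid) by construction; camera with an estimated correlation also missed the simulated shift. Over 14 settings the adjusted p ranged from 1.3e-30 to 0.787 for the sterol list, from 4.1e-10 to 0.787 for the fatty acid list and from 0.000783 to 0.875 for G2/M. With rGAL1 2 counted as a control, which mixes the groups if its title is right, the fatty acid median was -0.079 and did not pass. In that fit G2/M passed, but 1 array stood for rGAL1, with no spread of its own. Without 1 array the sterol median ranged from -0.30 to -0.25 (adjusted p at most 2.5e-08) and the fatty acid median from -0.16 to -0.086 (at most 0.0323); the lone array of a group is then assumed to vary like the other group. Of 52 named genes, 2 changed sign in some setting. EGFR was -0.030 with rGAL1 2 as a control and -0.023 to 0.11 without 1 array. GLI1 was -0.044 to 0.28 without 1 array. These 2 are the named genes whose arrays overlap between the groups. In the others both rGAL1 arrays lie on one side of both Ctrl arrays. Leaving out 1 array cannot turn their sign, so the count is no test of them. No named gene passed in any setting run (smallest adjusted p 0.562). The robust prior was not run on lists, as camera has no such option, nor the 1-symbol filter, which lists already meet, and both planned dim filters came to the same level. Signal over background could not be judged without detection calls.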

Other observations

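The tests on other splits of the arrays, on rGAL1 2 and on symbol families were chosen after the results were seen; those on brightness and LXR targets were written before theirs. Outside the fixed lists, genes were grouped by the letters that open their symbols, and 2 of 101 such families with at least 15 members passed camera (limma) with the preset correlation. CEP genes, which encode mainly centrosomal proteins, had higher means in 30 of 38 members, with a median of 0.11 (adjusted p = 0.0181), which was 0.052 without Ctrl 2. The family of small Cajal body RNAs had lower means in 20 of 23, with a median of -0.097 (adjusted p = 0.0181). Both kept their direction under the 3 other normalizations. Both calls were lost with an estimated correlation (camera adjusted p = 0.960), a setting that also missed the simulated sterol shift and so cannot decide here. MicroRNA genes, 1098 in number, had a median of -0.031, and 458 long intergenic RNAs a median of -0.0078.

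Brightness does not account for the lower level of sterol synthesis genes, since 0% of 10000 random lists matched on expression had a median as low as -0.27. Whether rGAL1 2 is a control array, as its treatment field reads, stays open: it lay below both Ctrl arrays in 18 of 18 sterol genes, where 32.1% of all named genes did so, with a median of -0.30 against the Ctrl mean where the Ctrl arrays differed by a median of 0.034 in size. But the list was noticed with rGAL1 2 in its group, 2 Ctrl arrays do not show how far controls can differ, and over all probe sets rGAL1 2 and Ctrl 1 were the closest of the 6 pairs of arrays (SD of the difference 0.27, against 0.29 for the rGAL1 pair). Of the 3 ways to split the 4 arrays into pairs, 1 called the list, the real one, with a median of 0.27 in size against 0.036 at most in the others; 3 splits are too few for a share under 0.05. A response to rGAL1 is a candidate explanation, but its vehicle, the feeding or density of the cultures and an array batch that followed the groups stay open, as the labels give none of these.

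As a hypothesis, loading of the treated cells with lipid could lower SREBP targets and at the same time raise targets of LXR, the oxysterol receptor. Of 17 LXR targets listed beforehand, 6 were named outside the tested lipid lists, and their median was -0.035 (95% bootstrap interval over genes -0.13 to 0.030), with 5 of 6 lower; the hypothesis asked for more than 0.1. The predicted rise was thus not seen in these 6 genes, MYLIP, LPCAT3, LPL, APOC1, APOE and PLTP. The interval covers the spread between genes and not between arrays. The SEs of the single genes were 0.099 to 0.14, and LPL, with a mean of 3.76, lay below the dim level. A modest LXR response therefore stays open, as does lipid loading without one.

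The number of probe sets at an unadjusted p under 0.05 was counted for each of the 3 splits. The real split gave 2807, the split by replicate number 2473 and the crossed split, Ctrl 2 and rGAL1 1 against Ctrl 1 and rGAL1 2, 3075, so 2 of the 3 splits, the real one included, gave at least as many as the real one; 3 splits are too few for a share under 0.05. The split by replicate number called 1 list, G2/M and mitosis, lower in the arrays numbered 2 (median -0.077, camera adjusted p = 0.00638), a larger median than the 0.053 between the groups.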
